A study of Homo sapiens with 2 samples.

How the data were processed

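Total RNA from the human cell lines NK92 and YT was hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, with 1 array per line. Both lines are malignant lymphoid lines with natural killer (NK) features. The deposited values are scaled intensities on a linear scale, extracted by the authors with Affymetrix Microarray Suite; the software version is not given in the sources used here. Scaling to a target of 500 was tested on the values: the mean after trimming 2% at each end was 500.03 on the NK92 array and 500.06 on the YT array, so the deposited scale was kept. Each array holds 54675 probe sets, and no column of values was left unused (0).

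Probe sets were assigned to genes with the platform annotation. Of all probe sets, 41091 matched 1 gene, 1801 matched several genes, 11721 had no gene used here and 62 were controls. Probe sets of several genes, without a gene or for controls were left out, as were 59 probe sets of Y-linked genes and XIST. The remaining 41032 probe sets cover 19740 genes. A gene was represented by its probe set with the highest mean log2 intensity over both arrays. Gene order came from the RefSeq annotation of GRCh38.p14, in which 19735 of 19777 gene identifiers were matched.

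The background of each array was the 95th percentile of 101 probe sets of tissue-restricted genes, such as those of liver, retina and skeletal muscle, of which 57 of 68 listed were on the array. This gave 357.5 intensity units for NK92 and 588.5 for YT. Values below the background were set at it, so the ratio of a gene above background on a single array is a bound and is written as "at least". Where the brighter array did not exceed the background of the other array, the log2 ratio was set to 0. Such a 0 means that the arrays could not be ordered, not that their signals were equal. Genes counted as within 2-fold include these and bounds under 2-fold, whose ratio may be larger. A gene counted as higher in a line when it was above background there and the ratio was at least 2-fold. The log2 ratios are YT over NK92 throughout.

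With 1 array per line there is no spread between cultures, so no test and no p-value can be given, and no paired analysis was possible. The number of arrays limits the precision. The only repeated measurement is that between probe sets of the same gene. Among 2369 genes with several probe sets above background on both arrays, the pooled SD of the log2 ratio between probe sets was 0.32, which is 1.25-fold. It covers probe error and transcript differences, not differences between cultures.

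There were 32 gene lists, and a list was summarised where at least 3 of its members were above background on at least 1 array. The median log2 ratio of those members was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. Bounds entered these medians as values, so a list median can itself be a bound. Lists beyond the central 95% of random lists on either side are described as lying outside it. For chromosomal neighbourhoods, medians were taken over windows of 20 neighbouring genes above background. They were compared with the most extreme windows of 100 permutations of the ratios within expression bins. Overlapping windows past the permutation limit were joined into regions.

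The genes named are the 12 with the largest ratio in each direction, the largest 2 of each list in each direction past 2-fold, and a fixed set of 10. The first group was restricted to genes whose brighter array exceeded the 75th percentile of its probe sets (442.6 units in NK92, 473.6 in YT) and whose other probe sets above background had the same sign. The fixed set is NCAM1, FCGR3A, CD28, GZMB, PRF1, IL2RA, CISH, BCL2, MYC and EBI3, of which FCGR3A is not reported here. Other genes are named only where the text says that they were chosen after their values were seen. Gene lists, background genes, the size rule, the naming rule and the first group of alternatives below were fixed before the data were examined.

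The alternatives fixed in advance were quantile normalization, centring on the median, the median over all probe sets of a gene, only probe sets of the unmodified _at type, a background at the 99th percentile, and a pseudocount of 50 without a background floor. A 4-fold size rule, the mean of a list in place of its median and random lists not matched on expression belonged to the same group. A common background for both arrays, a background list without MBP and ALB, and scaling on the hybridisation controls were added after seeing the data. The 99th percentile was 3647.7 units in NK92 and 3053.9 in YT. Both are values of MBP probe sets, and MBP had clear signal on both arrays, so this setting is a strict intensity cut rather than a background.

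The procedure was tested on simulated data. Of 40 lists of 15 genes shifted by 0.5 log2, 27 lay outside the central 95% (67.5%), against 40 of 40 for a shift of 1 and 2 of 40 without a shift. A window of 20 genes shifted by 1 log2 was found in 7 of 10 runs, with 0 regions elsewhere. Of 200 genes raised 4-fold, 199 were called, and 17 of 8107 unchanged genes were called (0.21%). The spread between cultures is not known from 1 array per line, so 0.21% is not the share of false calls in the data. All computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.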

Results

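Gene expression was compared between NK92, an NK lymphoma line grown with interleukin-2, and YT, an NK-like leukaemia line. Each line was measured on 1 array, without replicates. The lines were cultured differently. NK92 received 10 ng/mL interleukin-2 in 75% α-MEM with horse serum and fetal bovine serum at 12.5% each and L-glutamate at 2 mM. YT grew in IMDM (80%) with fetal bovine serum (20%), with no interleukin-2 named. Line and medium therefore cannot be told apart in any value given here.

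The median intensity was 68.1 on the NK92 array and 70.6 on the YT array, and the highest was 41812 and 43887. Above background lay 14987 probe sets in NK92 (27.4%) and 12233 in YT (22.4%). The ratio of 3' to 5' signal was 0.990 in NK92 and 0.900 in YT for GAPDH, and 1.31 and 1.38 for ACTB. Of 18 hybridisation control probe sets, 17 were higher in YT, by a median of 1.16-fold. Across 41032 probe sets, which are not independent replicates, log2 intensities of both lines correlated with r = 0.856 (Spearman's rho 0.854). Across the 9761 probe sets above background on both arrays, r was 0.802 and rho 0.756.

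YT had the higher signal for MHC class II genes, hypoxia response genes and p53 target genes. NK92 had the higher signal for NK receptors, secreted chemokines, interferon-stimulated genes and cholesterol synthesis genes. HLA-DRA, the invariant chain gene CD74 and the glycolytic enzyme gene ALDOC were at least 64.9-fold, 60.6-fold and 41.3-fold higher in YT. GZMK, which encodes a granzyme, and the chemokine genes CCL18 and CCL4 were at least 37.2-fold, 29.5-fold and 24.5-fold higher in NK92. Both lines had high signal for the cytotoxic effectors granzyme B and perforin.

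Of 8087 genes above background on at least 1 array, 1015 were at least 2-fold higher in YT and 741 at least 2-fold higher in NK92, together 21.7%. Of these, 340 in YT and 242 in NK92 rest on a bound because the other array was not above background. At 4-fold the counts were 211 and 163. The share of calls higher in YT, 57.8%, depends on the scaling and on the background. It was 39.9% when the arrays were scaled on the hybridisation controls, which moved the median log2 ratio of all genes to −0.13. With the background at the 99th percentile it was 36.5%. A common background gave 50.3%, with 749 genes higher in YT and 741 in NK92, and the pseudocount 49.9%. Without MBP and ALB in the background list the share was 60.1%. In the main setting the YT background was the higher, so a gene above background only in NK92 needed more signal to be called. Among genes with several probe sets above background on both arrays, 397 passed 2-fold, and in 381 of them (96.0%) all these probe sets had the same sign. Probe sets above background on a single array did not enter this count.

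**Figure D1:**
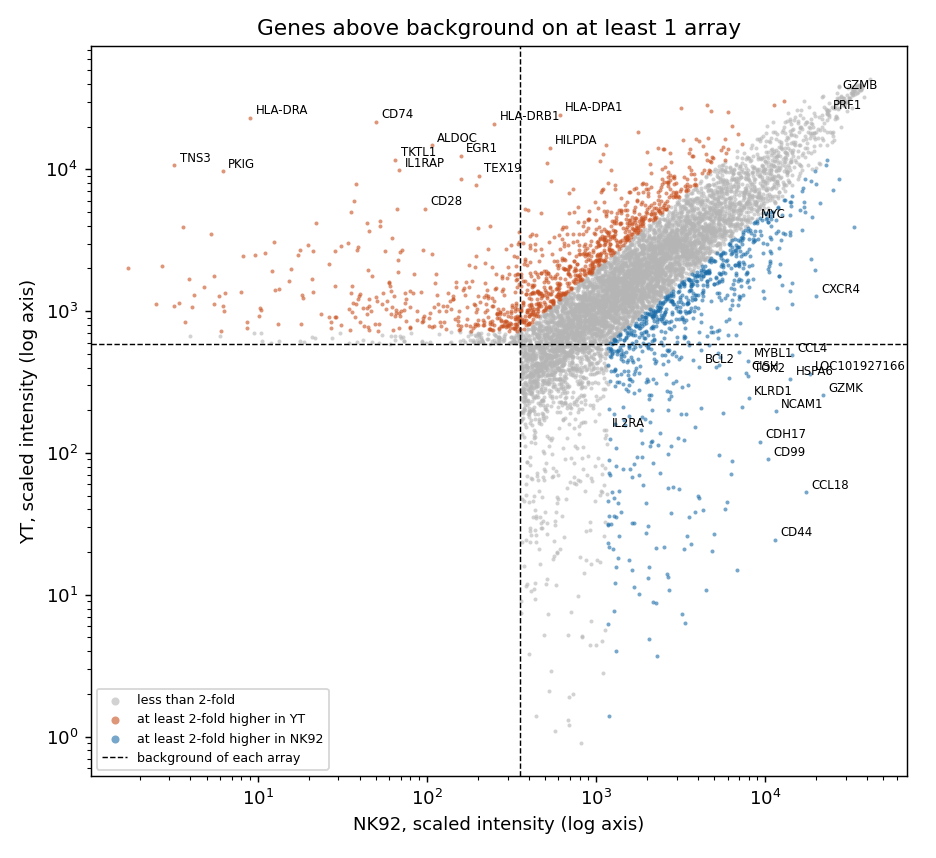
Scatter plot of gene intensities on the YT array against the NK92 array, both on log axes in scaled intensity units, each point a gene. The backgrounds are 357.5 for NK92 and 588.5 for YT, and 1015 genes are at least 2-fold higher in YT against 741 in NK92.

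Outside the gene lists, the largest ratios in favour of YT included EGR1, an immediate early transcription factor gene, at least 35.0-fold higher, with 12496 units in YT and 158.4 in NK92. TKTL1, a transketolase-like gene, was at least 32.6-fold higher, and TNS3, which encodes a focal adhesion protein, at least 29.8-fold. IL1RAP, a subunit of the interleukin-1 receptor, was at least 27.6-fold higher in YT, PKIG, a protein kinase A inhibitor gene, at least 27.2-fold, and TEX19 at least 25.2-fold. HILPDA, a lipid droplet protein gene, was 26.6-fold higher in YT, at 14211 against 533.9 units. The probe sets of EGR1 ranged from 1.17 to 5.13 log2. In the other direction, LOC101927166 was at least 31.2-fold higher in NK92. HSPA6, an inducible heat shock protein gene, was at least 23.9-fold higher, with 14073 units in NK92 and 333.3 in YT, not above background. The adhesion genes CD44, CD99 and CDH17 were at least 19.5-fold, 17.6-fold and 15.9-fold higher in NK92. The log2 ratio of CD44 ranged from −4.29 to −1.19 over its probe sets. MYBL1, which encodes a MYB-family transcription factor, was at least 13.5-fold higher in NK92.

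Among 19 cytotoxic granule and death effector genes above background, 7 were higher in NK92, 1 was higher in YT and 11 were within 2-fold. The list median of −0.43 log2 lay at percentile 1.23 of random lists. It was inside the random range with only _at probe sets (−0.41, percentile 3.31), and the list mean was −0.76. GZMB was close in both lines, with 26659 units in NK92 and 34850 in YT (1.31-fold), as was PRF1, with 23368 and 25153 (1.08-fold). GZMA was 8.56-fold higher in NK92, at 33520 against 3915 units, while GZMH was 2.37-fold higher in YT.

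Activating NK receptors and their adaptors had a median of −1.73 log2, below all 10000 random lists (percentile 0). Of 14 genes above background, 8 were higher in NK92 and 1 in YT. The median was −1.002 with the background at the 99th percentile. SH2D1B, which encodes the adaptor EAT-2, was at least 11.8-fold higher in NK92, and NCR3, which encodes NKp30, at least 9.56-fold. KLRC3 was the exception, 3.04-fold higher in YT. Inhibitory and KIR-family receptors had a median of −0.72 log2 (percentile 0.14), with 5 of 11 higher in NK92 and 0 higher in YT; probe sets of KIR genes can cross-hybridise. With the background at the 99th percentile this list was inside the random range (−0.64, percentile 3.14), and without MBP and ALB in the background list its median was −0.28 (percentile 2.38). KLRD1, which encodes CD94, was at least 13.6-fold higher in NK92 and KLRB1, which encodes CD161, at least 7.62-fold. NCAM1, the gene of the NK marker CD56, had 11570 units in NK92 and 196.3 in YT, at least 19.7-fold apart (−4.30 log2). Another probe set of NCAM1 was set to 0 log2, with no order between the arrays.

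NK and innate lymphoid transcription factor genes had a median of −0.23 log2 (percentile 6.6), inside the random range, and a mean of −0.59 (percentile 0.29), outside it. Of 18, 5 were higher in NK92 and 2 in YT. TOX2 was at least 13.5-fold and IKZF2, the Helios gene, at least 9.12-fold higher in NK92, whereas LEF1, a mediator of Wnt signals, was at least 3.15-fold and ZEB2 at least 2.19-fold higher in YT. T-cell receptor complex and co-receptor genes had 8 members above background, 4 higher in NK92 and 1 in YT, with a median of −0.63 log2 (percentile 3.48). TRAT1 was at least 7.88-fold and CD3E 4.82-fold higher in NK92. CD28, a co-stimulatory receptor gene, was at least 14.8-fold higher in YT, at 5287 units, while its NK92 value was not above background. The T-cell receptor genes are among those whose probe sets can cross-hybridise.

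Markers of other blood cell types were mostly below background. B-cell markers had 3 of 12 measured members above background, 1 of them higher in NK92, with a median of −0.65 log2 (percentile 5.67). This median is itself a bound, from a gene above background in NK92 only. It was −1.60 without MBP and ALB in the background list and −3.56 with a pseudocount and no floor, both outside the random range, as it was with the median over probe sets (percentile 1.2). CD79A, a B-cell receptor component, was at least 3.59-fold higher in NK92. A single myeloid marker of 12 was above background, ITGAM, at least 2.24-fold higher in NK92. A single erythroid and stem-cell marker of 9 was above background, KIT, at least 2.40-fold higher in NK92.

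Genes of the interleukin-2 and STAT5 response had a median of −0.97 log2 (percentile 0.01), with 8 of 17 higher in NK92 and 3 in YT. Its median with only _at probe sets was −0.50 log2, inside the random range at percentile 2.76, and −0.52 with the background at the 99th percentile. CISH, a STAT5-induced signalling inhibitor, had 7752 units in NK92 and 364.9 in YT, at least 13.2-fold apart. BCL2, an anti-apoptotic gene, was at least 6.95-fold higher in NK92 by its brightest probe set. Another probe set of BCL2 was set to 0 log2, with no order between the arrays. IL2RA, the alpha chain of the interleukin-2 receptor, had 1152 units in NK92 and 144.7 in YT, a bound of 1.96-fold. The list median of −0.97 log2 equals this bound, so it is itself a bound. BCL6, a transcriptional repressor, was 7.10-fold higher in YT and SOCS3 at least 5.40-fold. MYC was 2.06-fold higher in NK92.

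Cytokine receptor genes went both ways, with 3 higher in YT, 3 higher in NK92 and 12 within 2-fold (median −0.16 log2, percentile 16.6). TGFBR1 was at least 8.97-fold and IL18RAP, a subunit of the interleukin-18 receptor, 6.84-fold higher in NK92. Another probe set of TGFBR1 was set to 0 log2, with no order between the arrays. IL6ST, which encodes gp130, was 6.76-fold higher in YT and IL1R1 3.12-fold. Secreted cytokines and chemokines had a median of −1.47 log2, below all random lists (percentile 0), with 6 of 10 higher in NK92 and 0 in YT. The median was −2.49 with a pseudocount and no floor. In that list, IL16 was at least 10.8-fold higher in NK92, after CCL4.

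Chemokine and homing receptors had a median of −0.07 log2 (percentile 23.9), with 3 of 14 higher in NK92 and 1 in YT. CXCR4 had 19942 units in NK92 and 1274 in YT (15.7-fold), and CCR1 was 5.48-fold higher in NK92. CCR7, the lymph node homing receptor gene, was at least 3.50-fold higher in YT. NF-kB response genes were close between the lines, with 9 of 10 within 2-fold and a median of 0.15 log2 (percentile 76.4). IER3 was at least 2.12-fold higher in YT. EBI3, a cytokine subunit gene of that list, was not above background on either array (10.3 units in NK92 and 2.9 in YT).

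Interferon-stimulated genes had a median of −1.31 log2, below all random lists (percentile 0), and 10 of 19 were higher in NK92. The median was −0.80 over all probe sets of each gene, −0.73 with only _at probe sets and −0.54 with the background at the 99th percentile. IFI27 was at least 8.50-fold and MX1, an antiviral GTPase gene, at least 4.45-fold higher in NK92. OASL, of the oligoadenylate synthetase family, was 2.04-fold higher in YT.

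MHC class II genes had a median of 3.98 log2, above all random lists (percentile 100), and all 10 members above background were higher in YT. The median was 2.52 with the background at the 99th percentile. HLA-DRA had 9.0 units in NK92 and 23191 in YT, and CD74 had 49.9 and 21675. HLA-DRB1 was at least 58.6-fold and HLA-DPA1 39.98-fold higher in YT. Probe sets of HLA genes can cross-hybridise, so values of single members are less certain than the direction of the group. MHC class I and antigen processing genes had a median of −0.42 log2 (percentile 2.74), with 14 of 16 within 2-fold. TAP2 was 3.32-fold higher in NK92 by its brightest probe set, with probe sets from −1.73 to 1.22 log2, and PSMB9, an immunoproteasome subunit gene, 2.29-fold higher in NK92.

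p53 target genes had a median of 1.65 log2, above all random lists (percentile 100), with 8 of 12 higher in YT and 0 in NK92. This median was 0.45 log2 with the background at the 99th percentile. GADD45A, a stress-induced growth arrest gene, had 728.5 units in NK92 and 7323 in YT (10.1-fold). TNFRSF10B, a death receptor for TRAIL, was 6.75-fold higher in YT. Apoptosis regulators had a median of 0 log2 (percentile 51.1), with 14 of 17 within 2-fold. The pro-apoptotic gene BAX was 3.68-fold higher in YT, and BID was at least 2.05-fold higher in NK92.

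Cell-cycle inhibitors and G1 cyclins had a median of 0.07 log2 (percentile 66.0), with 2 of 12 higher in YT and 3 in NK92. CDKN1A, the gene of the inhibitor p21, was at least 4.40-fold higher in YT and CCNE1 2.22-fold. CDKN2A, at 10650 against 2170 units, was 4.91-fold higher in NK92, and CCND2 was 4.12-fold higher there. Another probe set of CCND2 was set to 0 log2, with no order between the arrays. Proliferation genes had a median of −0.54 log2 (percentile 0.31), with 7 of 23 higher in NK92 and 0 in YT. The kinetochore motor gene CENPE was 3.08-fold and MCM3, a replication licensing gene, 2.96-fold higher in NK92.

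Hypoxia response genes had a median of 2.03 log2, above all random lists (percentile 100), with 6 of 9 higher in YT and 1 in NK92. ALDOC was at least 41.3-fold and ANKRD37 11.8-fold higher in YT. The median was 3.15 with only _at probe sets. NDRG1 was the exception, at least 3.56-fold higher in NK92. Glycolysis genes had a median of 0.48 log2 (percentile 99.6), with 2 of 17 higher in YT and 15 within 2-fold. The glucose transporter gene SLC2A3 was 2.08-fold higher in YT, next to ALDOC, which both lists hold. Scaled on the hybridisation controls, the glycolysis median was 0.26 log2, the list mean was 0.74, and with only _at probe sets the list was inside the random range (0.63, percentile 97.38). Oxidative phosphorylation genes had a median of 0.13 log2 (percentile 81.7), with 16 of 17 within 2-fold; that scaling put the median at −0.08. SDHC was 2.85-fold higher in NK92.

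Cholesterol biosynthesis genes had a median of −1.52 log2, below all random lists (percentile 0), with 7 of 14 higher in NK92 and 7 within 2-fold. The median was −0.82 with only _at probe sets and −0.97 with the background list without MBP and ALB. IDI1, an isoprenoid pathway isomerase gene, was 8.26-fold higher in NK92 by its brightest probe set, and EBP was 5.69-fold higher. Another probe set of IDI1 was set to 0 log2, with no order between the arrays. Heat shock and protein folding genes had a median of −0.77 log2 (percentile 0), with 5 of 14 higher in NK92 and 0 in YT. XBP1, an unfolded protein response factor gene, was 7.22-fold and the co-chaperone gene DNAJB1 4.07-fold higher in NK92. Serine, amino acid synthesis and ATF4 target genes had a median of −0.05 log2 (percentile 46.2), with 9 of 12 within 2-fold. SLC3A2 was 2.44-fold and ATF4 2.39-fold higher in NK92, and PSPH, a serine synthesis gene, 2.37-fold higher in YT.

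MicroRNA processing genes had a median of 0.08 log2 (percentile 67.2), with 11 of 12 within 2-fold; PRKRA was 3.88-fold higher in YT. Epigenetic regulators had a median of −0.10 log2 (percentile 28.9), with 13 of 14 within 2-fold; HDAC9, a histone deacetylase gene, was 5.86-fold higher in YT. The list of genes on the long arm of chromosome 6 had a median of −0.34 log2 (percentile 8.93), with 2 of 10 higher in NK92, FOXO3 by 4.36-fold and CRYBG1 by 3.66-fold. That list also holds PTPN2, which lies on another chromosome. Kinase and signalling genes had a median of −0.08 log2 (percentile 36.2), with 4 of 19 higher in YT and 3 in NK92. STAT4 was 6.14-fold and DUSP6 at least 4.72-fold higher in NK92, whereas the receptor gene PDGFRA was at least 7.02-fold and JAK3 2.28-fold higher in YT. All 16 ribosomal protein genes and all 14 reference genes were within 2-fold, with medians of 0.10 log2 (percentile 78.0) and 0.04 log2 (percentile 62.5). Scaled on the hybridisation controls, these medians were −0.11 and −0.18, and the reference gene median also became negative under quantile normalization (−0.02), the median over probe sets (−0.05), only _at probe sets (−0.20) and the background at the 99th percentile (−0.0025).

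**Figure D2:**
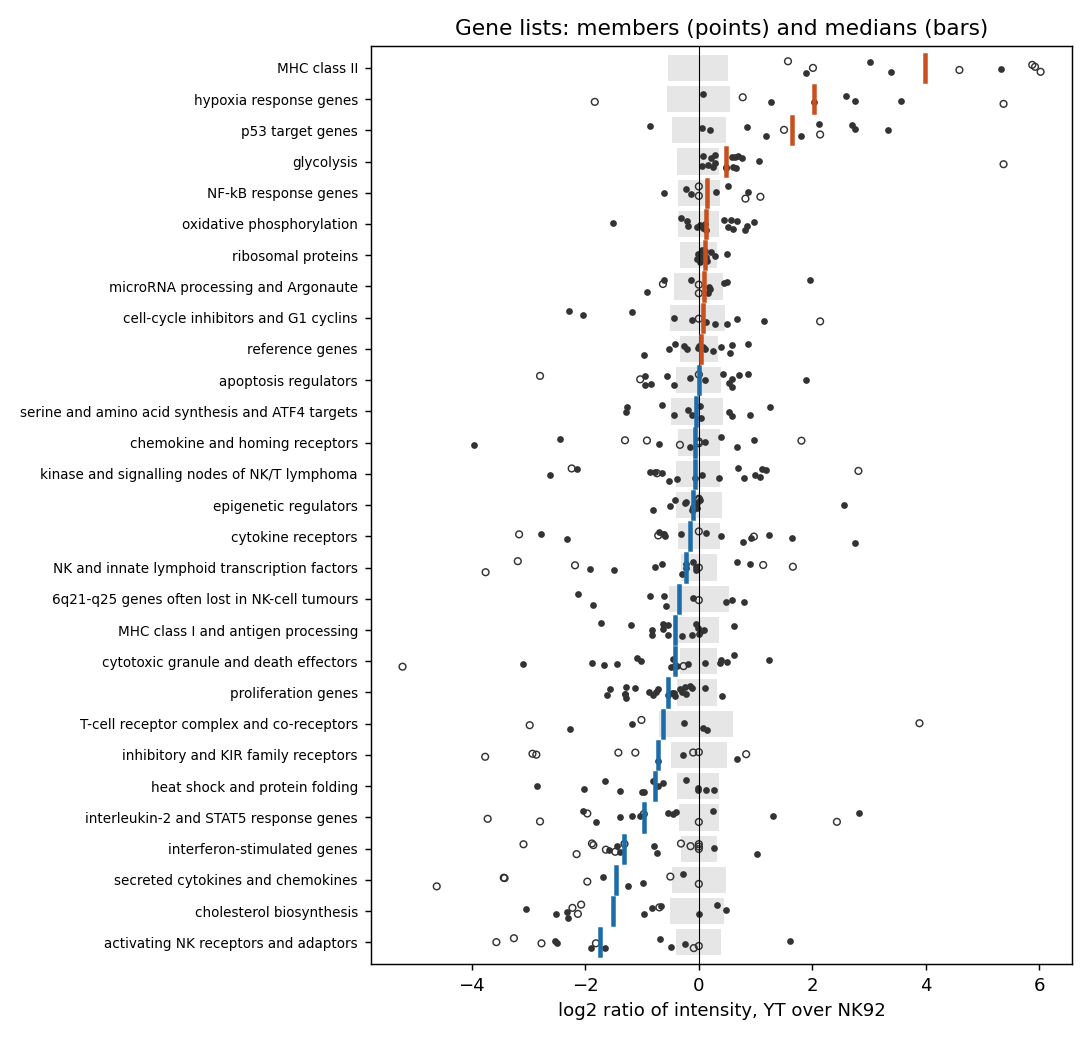
Log2 ratio YT over NK92 of list members, a line per gene list with at least 5 members above background, with filled points for genes measured above background on both arrays, open points for bounds and bars for list medians. The grey bands are the central 95% of random lists, drawn from their median and SD as a normal spread; MHC class II (3.98), hypoxia (2.03) and p53 targets (1.65) lie above them, and activating NK receptors (−1.73), cholesterol synthesis (−1.52) and interferon-stimulated genes (−1.31) below.

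Of the 32 lists, 30 had enough members above background; 4 of these lay above the central 95% of random lists, 9 below it and 17 inside.

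The sign of some medians inside the random range turned with the setting. With only _at probe sets, NF-kB response genes were at −0.14 and microRNA processing genes at −0.12. With the background at the 99th percentile, homing receptors were at 0.12 and cell-cycle inhibitors and G1 cyclins at −0.44. Kinase and signalling genes were at 0.0050 under quantile normalization, and serine and ATF4 genes at 0.0032 with the median over probe sets. With only _at probe sets, T-cell receptor genes were at −0.26 and the chromosome 6 list at 0.

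Some named genes were under 2-fold in another setting. MYC did so under quantile normalization and OASL under median centring, TAP2 and SLC2A3 with the median over probe sets, and BID and IDI1 with only _at probe sets. LEF1, ZEB2 and IER3 did so with a common background, and CCNE1 and JAK3 when scaled on the hybridisation controls. Another 18 named genes did so only with the background at the 99th percentile. Named genes above background on neither array in a setting, such as KIT and CDKN1A at the 99th percentile, had no value there and are not counted. Probe sets above background also spread by more than 1 log2 for CD74 (2.82 to 5.92), HLA-DPA1 (2.88 to 5.32), IL1RAP (3.55 to 4.78), CD28 (1.89 to 3.89), KLRD1 (−3.76 to −1.44), SH2D1B (−3.57 to −1.67), IL16 (−3.44 to −1.39), EBP (−2.65 to −0.97), DUSP6 (−2.24 to −0.99) and BID (−1.59 to −0.46).

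Expression ratios were also arranged by chromosomal neighbourhood. Over 7635 windows of 20 genes, the highest median was 1.98 log2 and the lowest −1.26, against permutation limits of 0.96 and −0.77. In 0 of 100 permutations was a window as high or as low as these extremes. The windows past the limits formed 14 regions with 455 genes, 5 higher in YT and 9 higher in NK92.

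The highest was a run of 25 genes on chromosome 17, from VPS53 to ITGAE, with a median of 1.76 log2 (3.39-fold). In it 15 genes were at least 2-fold higher in YT and 0 in NK92. Its members PRPF8, a core spliceosome gene, at 5.56-fold, and YWHAE, a 14-3-3 protein gene, at 4.21-fold, were chosen after their values were seen. The others higher in YT ran from ERICH1 to CHMP7 on chromosome 8 (35 genes, 1.05 log2), MRM2 to HNRNPA2B1 on chromosome 7 (48 genes, 0.99), FGF13 to IDH3G on the X chromosome (20 genes, 0.98) and MANBAL to TOMM34 on chromosome 20 (27 genes, 0.97). The last of these contains PKIG, and TOX2, which went the other way.

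On chromosome 6, 4 regions were higher in NK92: DTNBP1 to TRIM27 (40 genes, −0.93 log2), TJAP1 to GCLC (31 genes, −0.80), CRYBG1 to AMD1 (20 genes, −0.78) and BRPF3 to ZNF318 (43 genes, −0.76). On chromosome 15 these were FANCI to TM2D3 (31 genes, −0.99) and PPCDC to AEN (45 genes, −0.74). On chromosome 1 they were DCAF8 to MGST3 (29 genes, −0.75) and VAMP4 to XPR1 (27 genes, −0.71), and on chromosome 17 MYO1D to CWC25 (34 genes, −0.63). By whole chromosome, the median log2 ratio was 0.46 for chromosome 20, 0.27 for chromosome 14 and 0.13 for chromosome 5 (percentile 100 each), and 0.08 for each of chromosomes 12, 8 and 4 (percentiles 99.95, 99.2 and 98.8). It was −0.22 for chromosome 15 and −0.12 for chromosome 6 (percentile 0 each), and −0.06 for chromosome 22 (percentile 0.1). Random medians varied little, with an SD of 0.005 for chromosome 12 and 0.019 for chromosome 4, so small shifts reached extreme percentiles. Only the medians of chromosomes 20, 14 and 15 exceeded 0.21 log2 in size, the median difference of the hybridisation controls. The smaller ones are within what scaling could change.

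**Figure D3:**
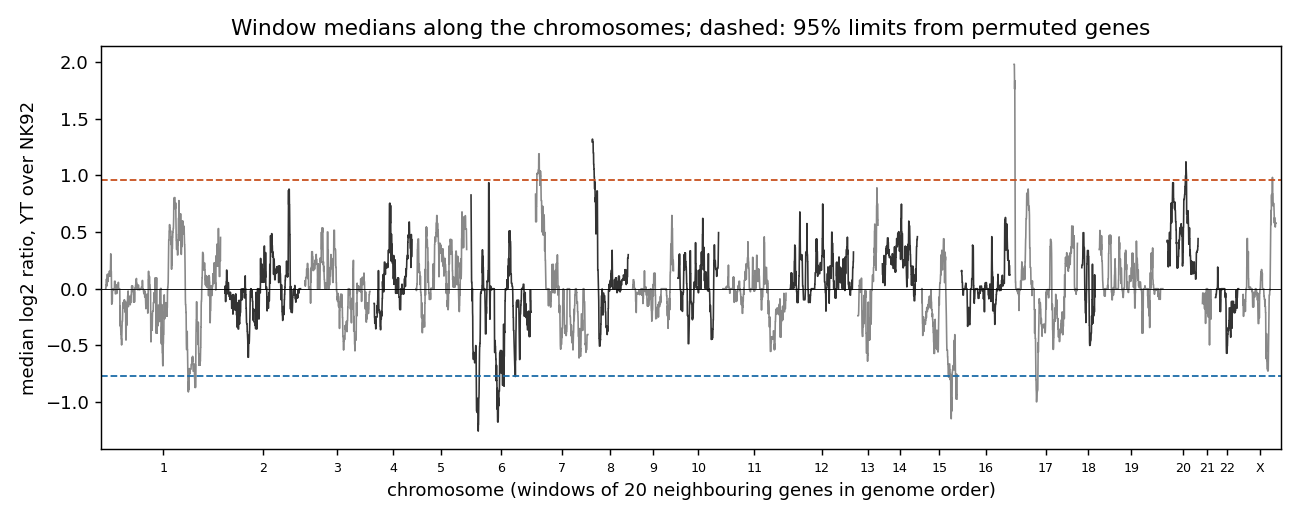
Median log2 ratio YT over NK92 in windows of 20 neighbouring genes along the chromosomes, in gene order. The limits from 100 permutations are 0.96 and −0.77; the highest window, at 1.98, is on chromosome 17.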

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

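The tests against chance order of genes (highest window and all regions), B or myeloid cells and cross-hybridisation between HLA genes were chosen after the results were seen; the other tests were written before. Probe sets of tissue-restricted genes served only to set the background, and 2 of these genes had signal above 2 times the background; a further one, SFTPB, was just above it in NK92 (363.8 units). ALB, the serum albumin gene, reached 4198 units on the YT array against 22 in NK92, and 2 of its 4 probe sets were above background in YT. MBP, the myelin basic protein gene, reached 3054 units on the YT array and 4085 on the NK92 array.

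Neighbouring genes shifted together between the lines in 14 regions. Chance order of genes is argued against for the highest window, which 0 of the 100 permutations that set the limits reached, and for the regions as a set, since 0 of 100 further permutations gave 14 regions and the most in any was 3; 13 of these gave at least 1, so a single region near the limits is less certain. Error of the chosen probe sets is argued against by 331 other probe sets of the same genes, which shifted by a median of 0.72 log2 in the direction of their region (SE 0.057 over probe sets). This SE treats probe sets as independent, although several can belong to 1 gene and all come from 1 array per line. It does not cover differences between cultures. Cross-hybridisation within clustered gene families is argued against because without genes that share a symbol stem 14 of 14 regions kept their direction, with medians of 0.84 to 1.76 log2 for those higher in YT and −0.99 to −0.44 for those higher in NK92; 5 of them had no such genes, and the region from MYO1D to CWC25 went from −0.63 to −0.44, so this is less certain there. A regional difference such as copy number remains a candidate explanation: 79 genes in the regions that took no part in the scan, because they were not above background on either array (values above 100 units), shifted by a median of 0.35 log2 in the same direction, above all 10000 random sets, but values this near the background are weak evidence and no DNA copy number was analysed here.

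Hypoxia response genes were higher in YT. Error of the chosen probe sets is argued against by 3 other probe sets of the list, with a median of 2.25 log2. A few outlying members are argued against by a further list of hypoxia-induced genes, with a median of 1.14 log2 over 14 genes, above all random lists. Oxygen or crowding of the YT culture at harvest could also give this pattern. It cannot be told apart from the line, because there was 1 culture per line.

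MHC class II genes were higher in YT. B cells or myeloid cells in the YT culture are argued against by their markers: 1 of 24 was above background on the YT array, PAX5 at 693.6 units. These markers had been counted before the test was chosen, so it is weak. The count also depends on the background. Without MBP and ALB, at 304.9 units in YT, CSF1R (325.7 units, picked after its value was seen) was above it too. CD74, HLA-DMA and HLA-DMB, which lie outside the classical HLA class II chains, were also higher in YT, with a median of 3.38 log2. This test was chosen when all 10 class II genes above background were already known to be higher in YT, so its outcome was largely fixed. It cannot show how far probe sets of the classical chains cross-hybridise. A difference between the lines themselves may underlie the pattern, as a hypothesis found on the same data; medium and line stay confounded.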

How the results depend on the processing

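Common background, background without MBP and ALB, and scaling on the hybridisation controls were added after seeing the data. The counts of 1015 genes higher in YT and 741 in NK92 stayed within 1.5 times under all alternatives but 2: 108 and 188 with the background at the 99th percentile, and 211 and 163 under the 4-fold rule, which by construction admit fewer genes. The share of calls higher in YT ranged from 36.5% to 61.2%. The lowest share came with the background at the 99th percentile, which lay at the signal of MBP probe sets (3647.7 units in NK92 and 3053.9 in YT). Of the calls, 96.2% were kept under quantile normalization, 97.8% under centring, 89.0% with the median over probe sets, 67.9% with only _at probe sets, 95.8% with the pseudocount, 16.9% with the background at the 99th percentile, 100% without MBP and ALB, 84.9% with a common background and 83.3% on the hybridisation controls. No list outside the central range reversed its direction.

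These medians (log2 YT over NK92) of lists outside the central range moved by more than the random-list SD. Changing or removing the background floor changes bounds by construction, and a changed background also alters which members count. The share of each was not tested, nor was any other cause unless named. With the median over probe sets, interferon-stimulated genes were at −0.80 and cholesterol synthesis at −1.10. With only _at probe sets, interleukin-2 response was at −0.50, interferon-stimulated genes at −0.73, cholesterol synthesis at −0.82, hypoxia at 3.15 and heat shock at −0.99. At the 99th percentile background, activating receptors were at −1.002, interleukin-2 response at −0.52, secreted cytokines at −1.05, interferon-stimulated genes at −0.54, MHC class II at 2.52, p53 targets at 0.45 and cholesterol synthesis at −1.78. With a pseudocount of 50, interleukin-2 response was at −1.16, secreted cytokines at −2.49, interferon-stimulated genes at −1.51, MHC class II at 4.88 and p53 targets at 1.90. With a common background, MHC class II was at 3.46 and p53 targets at 1.30. Without MBP and ALB, activating receptors were at −1.35, inhibitory receptors at −0.28, MHC class II at 3.47, p53 targets at 1.96 and cholesterol synthesis at −0.97. Scaling on the controls, which lowers ratios measured on both arrays by 0.21, put cytotoxic effectors at −0.64, activating receptors at −1.95, interleukin-2 response at −1.18, interferon-stimulated genes at −1.52, proliferation at −0.76, glycolysis at 0.26 and heat shock at −0.98. As means, cytotoxic effectors were at −0.76, activating receptors at −1.42, inhibitory receptors at −1.06, interleukin-2 response at −0.68, secreted cytokines at −1.81, interferon-stimulated genes at −0.97 and glycolysis at 0.74.

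Moved inside the central range were interleukin-2 response (percentile 2.76), cytotoxic effectors (3.31) and glycolysis (97.38) with only _at probe sets, and inhibitory receptors (3.14) at the 99th percentile background. Moved outside were apoptosis regulators (0.79), kinases (2.37) and oxidative phosphorylation (99.27) with only _at probe sets, T-cell receptor genes with the median over probe sets (2.1) and unmatched random lists (1.31), and MHC class I at the 99th percentile background (1.73), with a common background (1.96) and unmatched (1.42). NK transcription factors (0.29) and homing receptors (1.72) did so as means, homing receptors (2.48) without MBP and ALB, and B-cell markers with the median over probe sets (1.2), the pseudocount (1.48) and without MBP and ALB (0.98). Of 184 values of the 17 lists inside it, 27 moved and 18, in 9 lists, had the other sign. Of 87 named genes past 2-fold, 29 were under it in some alternative. Of 736 values, 733 had the same direction, 3 were set to 0 with no order between the arrays, and 0 were reversed. B-cell markers gave no value with only _at probe sets and at the 99th percentile, nor did NF-kB genes at the latter. Regions numbered 13 under quantile normalization and the median over probe sets, and 12 with a common background. Signal limits bounds: 459 genes were above background in YT only, 1368 in NK92 only.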

Other observations

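The test of the further hypoxia list was written before its values were seen. In that list, which shares no gene with the hypoxia response list, 7 of 14 genes above background were higher in YT, 0 higher in NK92 and 7 within 2-fold (median 1.14 log2). The last 7 include genes whose ratio is not resolved. PLIN2 had 567.5 units in NK92 and 18.7 in YT, and its log2 ratio was set to 0 because the NK92 value was under the YT background. PFKFB3 had a bound of 1.93-fold towards YT. GYS1, the glycogen synthase gene, was 6.57-fold higher in YT, and PLOD2, a collagen-modifying enzyme gene, at least 5.49-fold. WSB1 was 4.94-fold and FAM162A 4.25-fold higher in YT. These members were named after their values were seen.

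CIITA, which encodes the master activator of MHC class II transcription, was not above background on either array (209.4 units in NK92 and 287.3 in YT), while the class II genes were bright in YT. Without MBP and ALB in the background list, the background was 122.5 units in NK92 and 304.9 in YT, so CIITA was above it in NK92 but not in YT. This follows from the unequal backgrounds, since the CIITA value itself was the higher in YT, and it does not order the lines. CIITA was looked at after the class II values were seen.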
